A study of Mus musculus with 11 samples.

How the data were processed

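RNA was measured by sequencing in 11 libraries of sorted adrenal cells from 6 male Nestin-GFP mice, whose cortical and medullary tissues were pooled in 3 groups of 2 mice per the labels' protocols. The protocols describe digestion with collagenase, lysis of red blood cells, sorting with propidium iodide, 180 to 300 cells per tube, cDNA primed on the poly(A) tail with template switching, 17 cycles of PCR and fragmentation by a transposase. The kit carries no molecular identifiers and marks no strand. PCR reads without molecular identifiers are not independent molecules, so the counting intervals and floors given here cover counting error only. Mice were about 3.5 or 2.5 months old per the labels. In both gates of the cortex, libraries 1 and 2 came from the older mice and library 3 from the younger. In the medulla, GFP-positive library 1 and both GFP-negative libraries came from the older and GFP-positive libraries 2 and 3 from the younger. Age and gate are partly confounded there and in the interaction. Labels number the libraries but tie none to a pool or mouse, and gates can share animals. With 1 age per pool, these ages put 2 libraries of a group in 1 pool. P-values therefore measure the spread between libraries, part of which may be technical. No libraries of a group agreed within sampling noise, as 1 library deposited under 2 names would (chi-square per degree of freedom of 29.1 to 104 over the pairs), so each was counted as 1 sample.

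The authors deposited a table of whole-number counts of reads per gene, not normalized, for all 11 libraries. The submitters' processing notes name bcl2fastq 2.19.1, GSNAP, featureCounts 1.6.0, DESeq, DESeq2 1.18.1 and the mouse build mm10, without their roles. The authors also deposited 3 tables of comparisons, with log2 fold changes, their standard errors and test statistics per the file headers. In the same tables the authors deposited p-values and adjusted p-values, which from the test statistic behave as a test against an absolute log2 fold change above 1, beside a weight column. These tables also hold, as deposited, a normalized signal per library, which is the counts divided by 1 size factor per library, and 17 of 17 such columns matched their own library in the count table. The GC content of each gene in percent and its length are as the authors deposited them and were not used in any test.

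The count table holds 49671 genes, of which 34475 had a count in some library, and 92 external spike-in sequences with 10 counts in all, which were left out. Symbols came from the authors' deposited tables for 25509 genes and from a reference table for 23915, and 247 identifiers had none. Coordinates are those of mm10. Libraries were grouped by tissue and gate from their titles. Total counts lay between 18500690 and 29204212, and 3 counts, used as the floor where a group had none, correspond to 0.103 to 0.162 CPM, the usual unit of counts scaled by library size. CPM were computed with TMM-scaled library sizes.

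Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) after filterByExpr by group and TMM scaling. All 11 libraries entered 1 fit, with 7 residual and a median of 3.2 prior degrees of freedom. The common biological coefficient of variation was 0.479, and the prior count of 2 did not enter fitted changes. P-values of 20893 genes were adjusted after Benjamini and Hochberg within each comparison, at a threshold of 0.05. The comparisons were GFP-positive against GFP-negative cells in each tissue, cortex against medulla in each gate, and the interaction of gate and tissue. Where a group had no count, the fold is a bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with an exact 95% counting interval.

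Gene lists, 23 in all, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives given below as set beforehand. The lists cover reporter and progenitor genes, Schwann cells and glia, chromaffin cells, the neuronal cytoskeleton, steroidogenesis, the zona glomerulosa, the capsule and stem cells of the cortex, cholesterol synthesis, endothelium, pericytes and smooth muscle, fibroblast matrix, basement membrane, macrophages, lymphocytes and granulocytes, erythroid cells, adipocytes, proliferation, dissociation stress, Notch, Wnt targets, hedgehog, glucocorticoid response and mitochondrially encoded genes. Some genes stand in more than 1 list, such as Cyp11b2 and Shh. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 3 members were tested, which left 22 lists, with p-values adjusted over lists. camera with an estimated correlation and fry were alternatives set beforehand. Members were also adjusted over the list alone. With an estimated correlation, the calls that held were those of the chromaffin and zona glomerulosa lists between GFP-positive cells of the tissues, and those of the chromaffin, stress and glucocorticoid lists between GFP-negative cells.

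Genes are named by a fixed rule. It takes Nes, Sox10, S100b, Star, Cyp11b1, Cyp11b2, Nr5a1, Th, Dbh, Pnmt, Chga, Gli1, Shh, Pecam1 and Rgs5 in each comparison, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 10 CPM and groups that do not overlap (the last condition not for the interaction), and up to 4 members per list with the smallest p. The results of some genes are not reported here. Unnamed predicted, mitochondrial and ribosomal genes were left out of the largest changes. Of the genes this rule gives, those printed from the lists and from the interaction were chosen with their values seen. Per-library values of Chgb, Scg2, Chga, Scg3, Gch1, Emcn and Pnmt were also chosen after they were seen.

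Alternatives set beforehand were the size factors of DESeq2 1.42.0, total counts alone, TMM without the 20 genes of most counts, no filter on low counts (34475 genes), a stricter filter of at least 5 CPM in at least 3 libraries (12791 genes), DESeq2's own test, limma with voom, robust estimation, fits of only the groups compared, the replicate number as a block, age as a covariate, and leaving out each library in turn. A test against a log2 fold change of 1 (glmTreat) was added after seeing the data. The pipeline was tested on simulated data with 200 changed genes among 20893. For the cortical GFP contrast it recovered 29.9% of genes changed 2-fold, 53.7% changed 4-fold and 83.3% changed 8-fold, of 20026 genes tested there, and for the interaction 0%, 25.4% and 47% of 20061. Reads of close paralogs may be split between them (Cyp11b1 and Cyp11b2, Aldh1a1 and Aldh1a7, Agtr1a and Agtr1b, Hsd3b1 and Hsd3b6, Abcb1a and Abcb1b, Ccl3 and Ccl4), and so may those of overlapping or antisense genes, since the protocol marks no strand. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.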

Results

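RNA was sequenced from small pools of sorted adrenal cells of male Nestin-GFP mice, in which green fluorescent protein (GFP) is expressed under regulatory sequence of Nestin, an intermediate filament gene used as a marker of neural and other progenitor cells. The adrenal gland has an outer cortex, which makes steroid hormones, and an inner medulla, whose chromaffin cells make catecholamines. The 2 parts were dissected apart, digested, and sorted into GFP-positive and GFP-negative cells. The 11 libraries fell into 4 groups: cortical GFP-positive (n = 3), cortical GFP-negative (n = 3), medullary GFP-positive (n = 3) and medullary GFP-negative (n = 2). Total counts per library ranged from 22221659 to 25179817 in cortical GFP-positive, from 24321018 to 26274085 in cortical GFP-negative, from 18500690 to 28648901 in medullary GFP-positive and from 24465910 to 29204212 in medullary GFP-negative cells. A floor of 3 counts corresponded to 0.103 to 0.162 CPM (counts scaled by library size) per library. The question, from the title and design of the series, was whether Nestin-positive cells with features of Schwann cell precursors stand at the origin of steroid-producing cells and of chromaffin cells. Levels below are mean CPM ± SD over the libraries of a group, with the n given here, and changes are log2 values with an approximate standard error (SE). This SE is the absolute log2 change divided by the square root of the F statistic of edgeR's test. It was not estimated from the fitted coefficient itself.

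Nes, the gene behind the reporter (ENSMUSG00000004891, chromosome 3, 87971078 to 87980451, mm10), was higher in GFP-positive than in GFP-negative cells of both tissues. In the cortex its level was 44.5 ± 8.19 CPM (SD, n = 3) against 6.40 ± 1.57 CPM (SD, n = 3), a log2 difference of 2.80 (SE 0.391, edgeR adjusted p = 0.00136). In the medulla it was 109 ± 60.2 CPM (SD, n = 3) against 21.1 ± 7.08 CPM (SD, n = 2), a log2 difference of 2.37 (SE 0.443, edgeR adjusted p = 0.00406). Every GFP-positive library lay above every GFP-negative library of its tissue. Medullary GFP-positive library 2 stood at 178 CPM, against 78.7 and 69.2 CPM in the other medullary GFP-positive libraries.

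**Figure D1:**
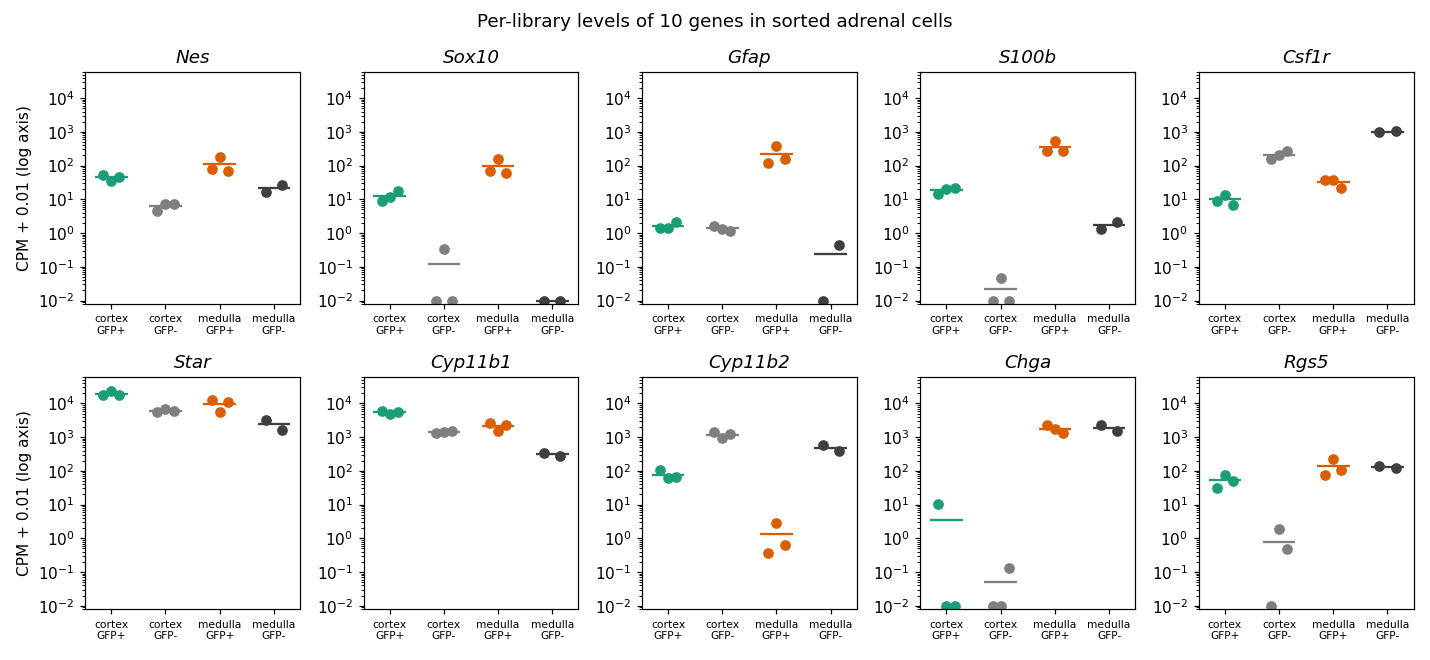
Levels of 10 genes in each of the 11 libraries, as CPM plus 0.01 on a log axis, by group. Points are libraries and horizontal bars are group means; Nes stood at 44.5 CPM in cortical GFP-positive against 6.40 CPM in cortical GFP-negative cells, and Cyp11b2 at 77.0 against 1183 CPM.

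In the cortex, GFP-positive cells held more glial, mural and matrix transcripts than GFP-negative cells, and less macrophage and zona glomerulosa transcript. Sox10, a transcription factor of neural crest and glia (ENSMUSG00000033006, chromosome 15, 79154913 to 79164490), stood at 12.8 ± 4.32 CPM against 0.110 ± 0.191 CPM (log2 6.76, SE 0.848, edgeR adjusted p = 0.00113). Both gates were rich in steroidogenic transcripts, and these divided by zone. Cyp11b1, the enzyme that completes corticosterone synthesis (chromosome 15, 74834125 to 74841643), was 3.91-fold higher in GFP-positive cells, at 5493 ± 480 against 1405 ± 105 CPM (edgeR adjusted p = 0.000163). Cyp11b2, the aldosterone synthase of the zona glomerulosa (chromosome 15, 74851010 to 74856318), was 15.4-fold lower, at 77.0 ± 22.4 against 1183 ± 219 CPM (edgeR adjusted p = 0.000967).

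edgeR's quasi-likelihood test called 3078 of 20893 genes, 1492 higher and 1586 lower in cortical GFP-positive cells, of which 2213 changed at least 2-fold. The groups did not overlap in 7980 genes, where chance gives 10% of genes for 3 against 3 libraries. With total counts alone 1244 genes were higher and 2032 lower. Without cortical GFP-negative library 3 the calls numbered 1959.

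Among the genes with the largest increases, Cdh19, a cadherin of Schwann cell precursors, had 4024 counts in the 3 GFP-positive libraries and 1 in the GFP-negative ones, a CPM ratio of 4700 with a 95% counting interval of 844 to 186000. Gpr37l1, a glial receptor, stood at 20.6 CPM against 2 counts, a ratio of 816 with an interval of 225 to 6740. Fabp7, a fatty acid binding protein of immature glia, stood at 28.5 ± 37.2 CPM against 2 counts, a ratio of 1150 with an interval of 319 to 9530. S100b, a calcium-binding protein of glia and 1 of the genes named in each comparison, stood at 19.1 ± 4.08 CPM against 1 count, a ratio of 1520 with an interval of 272 to 60000. The sodium channel gene Scn7a rose by 10.71 on the log2 scale (SE 1.17), Apod by 10.04 (SE 1.17) and the collagen gene Col5a3 by 9.36 (SE 0.683). Aldh1a1, which makes retinoic acid, reached 2268 ± 979 CPM against 3.77 ± 2.66 CPM, and its neighbour and close paralog Aldh1a7 253 ± 130 against 0.343 ± 0.594 CPM. Among the largest decreases, Slamf7 fell by 8.21 on the log2 scale (SE 0.894), Cd300ld by 8.04 (SE 1.12), Tmem119 by 6.95 (SE 0.761), Fgd2 by 6.89 (SE 0.609), Havcr2 by 6.08 (SE 0.696) and H2-M2 by 5.93 (SE 0.954). The chemokine genes Ccl3 and Ccl4, which are paralogs, stood at 1.01 ± 0.874 and 2.5 ± 2.91 CPM against 157 ± 121 and 207 ± 125 CPM. The edgeR adjusted p values of these genes lay between 3.8e-05 and 0.00917, and with voom Fabp7 (adjusted p = 0.377), Apod (0.154) and Ccl3 (0.0756) were not called.

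Among the lists fixed beforehand, 25 of 34 Schwann and glial genes rose and none fell (27 adjusted over the list alone; camera adjusted p = 4.72e-31, and adjusted p = 0.0723 with an estimated correlation). Of 24 macrophage genes 21 fell and none rose (22 adjusted over the list alone; camera adjusted p = 4.64e-30, and adjusted p = 0.0723 with an estimated correlation). Csf1r, the receptor that macrophages need to survive, stood at 9.92 ± 3.54 against 209 ± 55.6 CPM, and Adgre1, which encodes the F4/80 antigen, at 4.20 ± 3.11 against 78.4 ± 12.3 CPM. Of 24 pericyte and smooth muscle genes 12 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 9.51e-08, and adjusted p = 0.191 with an estimated correlation). Rgs5 stood at 52.2 ± 21.3 against 0.770 ± 0.953 CPM, Notch3 at 20.6 ± 10.4 against 0.698 ± 0.414 CPM and Ndufa4l2 at 12.8 ± 5.81 against 0.413 ± 0.0995 CPM. Of 21 fibroblast matrix genes 7 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.000293, and adjusted p = 0.26 with an estimated correlation), among them Col6a1 at 255 ± 17.4 against 28.6 ± 3.16 CPM. Of 15 basement membrane genes 6 rose (7 adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.331 with an estimated correlation), with Col4a1 at 265 ± 44.3 against 103 ± 15.5 CPM. There were 8 pericyte and 4 fibroblast calls without cortical GFP-negative library 3, 2 basement membrane calls without cortical GFP-positive library 2, and 3 without cortical GFP-positive library 3 or cortical GFP-negative library 1 or 3.

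Steroid cell genes split within the cortex. Of 29 steroidogenic genes 9 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.00471, and adjusted p = 0.384 with an estimated correlation). Star, which brings cholesterol into mitochondria, stood at 19560 ± 2960 against 6112 ± 676 CPM (3.20-fold, edgeR adjusted p = 0.005), and Cyp11b2 was among the 4 that fell. Of 14 zona glomerulosa genes 7 fell and none rose (9 adjusted over the list alone; camera adjusted p = 7.04e-07, and adjusted p = 0.191 with an estimated correlation). The angiotensin receptor gene Agtr1b stood at 11.9 ± 5.22 against 214 ± 60.7 CPM and the adaptor gene Dab2 at 697 ± 36.1 against 3319 ± 337 CPM. Of 22 cholesterol synthesis genes 11 rose and none fell (13 adjusted over the list alone; camera adjusted p = 1.19e-06, and adjusted p = 0.191 with an estimated correlation). Cyp51 rose 2.99-fold and Dhcr7 3.24-fold. Nr5a1, the transcription factor that specifies steroid cells, did not pass the test, at 305 ± 77.5 against 285 ± 65.8 CPM, nor did Shh, at 5.67 ± 3.54 against 29.7 ± 6.40 CPM (edgeR adjusted p = 0.0587), which was called under 6 alternatives (adjusted p of 0.00717 to 0.0457), among them DESeq2 and voom. Of 17 Wnt target genes 7 fell (7 adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.191 with an estimated correlation), with Nkd1 3.90-fold lower. There were 6 calls of cholesterol synthesis genes without cortical GFP-negative library 2 and 7 without cortical GFP-positive library 1. Wnt targets had 3 calls without cortical GFP-positive library 3 or cortical GFP-negative library 2, and 4 without cortical GFP-positive library 1 or cortical GFP-negative library 1 or 3.

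Of 36 chromaffin genes 8 rose in cortical GFP-positive cells and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 3.85e-05, and adjusted p = 0.291 with an estimated correlation). Scg3, a granule protein gene, stood at 3.06 ± 0.30 CPM against no count, which makes it at least 81-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.000416). Gch1, whose enzyme makes a cofactor of catecholamine synthesis, was 6.32-fold higher, at 71.0 ± 8.02 against 11.2 ± 6.65 CPM (edgeR adjusted p = 0.00151). Both lay close together over the 3 GFP-positive libraries (3.39, 3.01 and 2.79 CPM of Scg3, and 68.5, 80.0 and 64.5 CPM of Gch1). Hand2, a transcription factor of sympathoadrenal cells, stood at 3.81 ± 1.71 CPM against 2 counts, a ratio of 152 with a 95% counting interval of 41.6 to 1260 (edgeR adjusted p = 0.000717, and adjusted p = 0.0608 with voom). The gene that fell was Scg5, another granule protein gene, 11.2-fold lower at 4.41 ± 2.51 against 49.4 ± 10.7 CPM (edgeR adjusted p = 0.000585). Dbh, which converts dopamine to noradrenaline, was at least 224-fold higher against a floor of 3 counts over the GFP-negative group (edgeR adjusted p = 0.0238), with 17.7, 0 and 7.97 CPM in the 3 GFP-positive libraries. Its call ended without cortical GFP-positive library 1 (edgeR adjusted p = 0.0535) and without cortical GFP-negative library 1, 2 or 3 (0.0593, 0.0585 and 0.0619), and with voom (adjusted p = 0.33). Of the granule protein genes whose values in each library were looked at afterwards, Chgb stood at 55.8 CPM in cortical GFP-positive library 1, 1.29 CPM in library 2 and 0 in library 3, Scg2 at 63.2, 1.29 and 0 CPM, and Chga at 10.6, 0 and 0 CPM. Chga stood at 3.52 ± 6.09 against 0.0394 ± 0.0682 CPM and Th at 0.460 ± 0.797 against 0.0124 ± 0.0216 CPM, and neither passed the test. Chga was called without cortical GFP-positive library 2 or 3 (edgeR adjusted p = 0.0353 and 0.0359) and with no filter on low counts (0.0345), and the fitted changes of Chga and Th turned negative without library 1. Pnmt had no count in any of the 6 cortical libraries, which allows up to 0.135 CPM in 1 library. The list had 5 calls without cortical GFP-negative library 1, 2 or 3, and 15 without cortical GFP-positive library 3.

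In the other lists of the cortex, 8 of 24 proliferation genes fell and none rose (9 adjusted over the list alone; camera adjusted p = 1.19e-06, and adjusted p = 0.26 with an estimated correlation). The mitotic kinase gene Cdk1 stood at 1.57 ± 0.587 against 17.8 ± 8.08 CPM, and the replication helicase gene Mcm6 at 25.8 ± 8.50 against 114 ± 17.6 CPM. Of 23 genes that respond to dissociation stress 2 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.00579, and adjusted p = 0.291 with an estimated correlation). Dusp1 was 3.70-fold lower, while Jun was 2.40-fold higher. Of 16 Notch pathway genes 4 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0124, and adjusted p = 0.26 with an estimated correlation). Of 13 mitochondrially encoded genes 6 rose (13 adjusted over the list alone; camera adjusted p = 2.05e-06, and adjusted p = 0.26 with an estimated correlation), with mt-Nd4 at 15000 ± 4090 against 6030 ± 559 CPM. The share of counts from all genes of the mitochondrial chromosome was 13.5% ± 3.06 against 7.20% ± 0.15. There were 3 proliferation calls without cortical GFP-positive library 2 or 3 or cortical GFP-negative library 1 or 2, 6 stress calls without cortical GFP-positive library 2 or cortical GFP-negative library 3, and 3 mitochondrial calls without cortical GFP-positive library 2 or cortical GFP-negative library 1.

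The remaining lists did not pass the set test in the cortex. Of 12 reporter and progenitor genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.139). Of 13 neuronal cytoskeleton genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.071), and 2 calls were left without cortical GFP-positive library 2 or 3. Of 18 capsule and stem cell genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.97), with a median change above 0 although the test pointed down. The hedgehog mediator Gli1 stood at 0.683 ± 0.569 against 0.0866 ± 0.117 CPM. Of 30 endothelial genes 1 rose over all genes tested and none adjusted over the list alone (camera adjusted p = 0.0955), and Pecam1 stood at 18.8 ± 11.4 against 12.8 ± 5.10 CPM. That 1 call was lost without cortical GFP-negative library 1 or 3. Of 13 hedgehog genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.575). Of 16 glucocorticoid-responsive genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.265), and 3 calls were left without cortical GFP-positive library 1 or 3 or cortical GFP-negative library 1 or 2. Only 5 lymphocyte and granulocyte genes could be tested, with 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.472) and a median above 0 although the test pointed down, and 2 were called without cortical GFP-positive library 1. Of 4 adipocyte genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.108), and 1 call was left without cortical GFP-positive library 3 or any 1 of the cortical GFP-negative libraries. Only 1 erythroid gene passed the filter, and it was not called in the cortex.

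**Figure D2:**
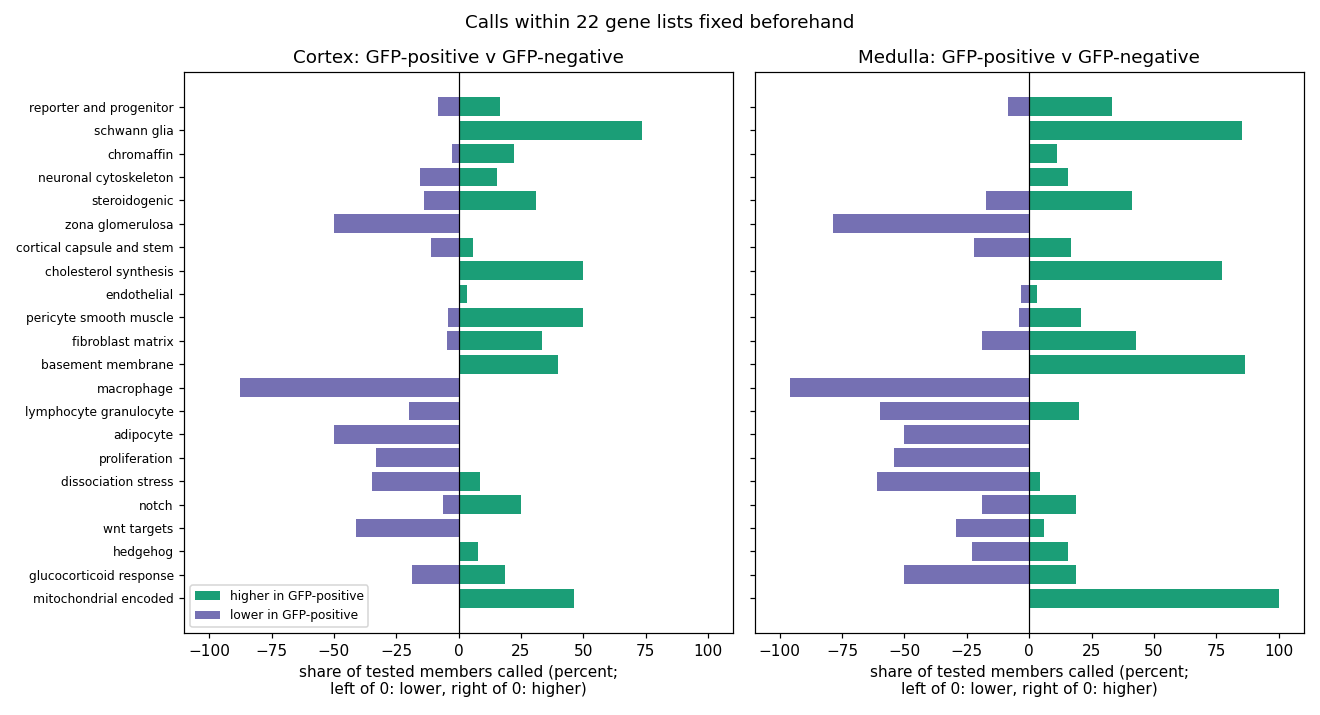
Share of the tested members of each of 22 gene lists that edgeR called higher (right of 0) or lower (left of 0) in GFP-positive cells, in percent, in the cortex and in the medulla. In the cortex 25 of 34 Schwann and glial genes were higher and 21 of 24 macrophage genes lower, and in the medulla 29 of 34 were higher and 23 of 24 lower.

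In the medulla, GFP-positive cells stood apart from GFP-negative cells by glial, basement membrane and cholesterol synthesis genes, while chromaffin genes were abundant in both gates. S100b stood at 356 ± 160 against 1.69 ± 0.535 CPM (log2 7.72, SE 0.507, edgeR adjusted p = 2.66e-05). Sox10 stood at 96.0 ± 54.1 CPM against no count, which makes it at least 1820-fold higher against a floor of 3 counts over the group. Th, the rate-limiting enzyme of catecholamine synthesis, did not pass the test, at 467 ± 205 CPM (SD, n = 3) against 462 ± 268 CPM (SD, n = 2). Chga, a granule protein of chromaffin cells, was likewise not called, at 1777 ± 519 against 1911 ± 513 CPM.

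The test called 4461 of 20893 genes, 2135 higher and 2326 lower in medullary GFP-positive cells, of which 3449 changed at least 2-fold. The groups did not overlap in 10052 genes, where chance gives a larger share than in the cortex because 1 group has 2 libraries. Higher calls outnumbered lower ones with total counts alone (2511 higher and 2174 lower) and with DESeq2 (2976 and 2951). Without medullary GFP-negative library 2 the calls numbered 2956.

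Among the genes with the largest increases, several had no count in GFP-negative cells. Against a floor of 3 counts over the group, Sostdc1 was at least 2240-fold, Nkain4 at least 2060-fold, the Wnt antagonist gene Sfrp5 at least 1170-fold, the potassium channel gene Kcna6 at least 1090-fold and Tex40 at least 798-fold higher. Foxd3, a transcription factor of neural crest and Schwann cell precursors, was at least 697-fold and Luzp2 at least 473-fold higher. Their edgeR adjusted p values lay between 0.00013 and 0.00228. Cyp11b2 fell by 8.45 on the log2 scale (SE 0.667), from 483 ± 119 to 1.29 ± 1.39 CPM, and Agtr1b by 9.47 (SE 0.783). Other large decreases were those of Asb2, by a log2 change of -8.40 (SE 1.41), Cd163 by -7.56 (SE 1.56), Cd69 by -7.11 (SE 1.64) and Sash3 by -7.04 (SE 1.14). Cxcl9 had 2 counts in GFP-positive cells against 27.8 ± 21.7 CPM, a ratio of 906 with a 95% counting interval of 250 to 7490, and Dusp2 stood at 0.450 ± 0.405 against 115 ± 119 CPM. The calls of Cxcl9 and Dusp2 ended without medullary GFP-negative library 2 (edgeR adjusted p = 0.0546 and 0.0574), and that of Dusp2 with voom (adjusted p = 0.063).

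Of 34 Schwann and glial genes 29 rose in medullary GFP-positive cells and none fell (31 adjusted over the list alone; camera adjusted p = 2.03e-27, and adjusted p = 0.0713 with an estimated correlation). Gfap, an intermediate filament of glia, stood at 216 ± 134 against 0.223 ± 0.316 CPM. Medullary GFP-positive library 2 held more of these transcripts than the others, with Sox10 at 158 CPM against 69.0 and 60.6 CPM. Of 24 macrophage genes 23 fell (23 adjusted over the list alone; camera adjusted p = 1.86e-25, and adjusted p = 0.0713 with an estimated correlation), with Csf1r at 31.8 ± 8.84 against 1006 ± 45.6 CPM and the mannose receptor gene Mrc1 at 12.1 ± 6.75 against 605 ± 48.8 CPM. Of 15 basement membrane genes 13 rose (13 adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.213 with an estimated correlation). Col4a1 rose 4.31-fold and Col18a1 10.4-fold. Of 21 fibroblast matrix genes 9 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.0146, and adjusted p = 0.363 with an estimated correlation), with Fbln2 at 150 ± 82.5 against 1.53 ± 0.877 CPM. In each of these matrix lists there were 7 calls without medullary GFP-negative library 1 and 8 without library 2.

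Steroidogenic transcripts were present in the medullary libraries and split in the same directions as in the cortex. Star stood at 9732 ± 3680 against 2394 ± 1050 CPM (4.06-fold, edgeR adjusted p = 0.00299) and Cyp11b1 at 2138 ± 521 against 309 ± 36.0 CPM (6.91-fold, edgeR adjusted p = 4.38e-05). Of 29 steroidogenic genes 12 rose and 5 fell (13 and 5 adjusted over the list alone), and the list did not pass the set test (camera adjusted p = 0.0507). Of 14 zona glomerulosa genes 11 fell and none rose (12 adjusted over the list alone; camera adjusted p = 9.42e-13, and adjusted p = 0.0713 with an estimated correlation). Dab2 stood at 62.8 ± 30.1 against 1725 ± 631 CPM and Shh at 1.03 ± 0.889 against 19.9 ± 2.10 CPM. Of 22 cholesterol synthesis genes 17 rose (18 adjusted over the list alone; camera adjusted p = 2.25e-12, and adjusted p = 0.0713 with an estimated correlation), with Cyp51 3.77-fold and Msmo1 5.16-fold higher. Nkd1 was 17.1-fold lower among 17 Wnt targets, of which 5 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00206, and adjusted p = 0.213 with an estimated correlation). Nr5a1 stood at 133 ± 32.1 against 141 ± 87.6 CPM and was not called. Without medullary GFP-negative library 2 there were 11 calls of cholesterol synthesis genes.

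Of 36 chromaffin genes 4 rose and none fell in medullary GFP-positive cells (3 adjusted over the list alone; camera adjusted p = 0.0405, and adjusted p = 0.546 with an estimated correlation), and none was called without medullary GFP-negative library 2. Dbh, at 647 ± 128 against 360 ± 68.0 CPM, was not called. Pnmt, which makes adrenaline, stood at 85.1 ± 114 against 6.78 ± 0.644 CPM and was not called, with 216 CPM in medullary GFP-positive library 2 against 6.61 and 32.3 CPM in the others, and it was called without medullary GFP-positive library 1 (edgeR adjusted p = 0.0399). Of 13 neuronal cytoskeleton genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.0371, and adjusted p = 0.442 with an estimated correlation). Of 24 pericyte and smooth muscle genes 5 rose and 1 fell without passing the set test (6 and 1 adjusted over the list alone; camera adjusted p = 0.0507). Notch3 stood at 9.22 ± 4.74 against 0.313 ± 0.132 CPM, and Rgs5, at 135 ± 77.4 against 128 ± 14.1 CPM, was not called. Of 30 endothelial genes 1 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.0405 for a decrease, and adjusted p = 0.663 with an estimated correlation). There was 1 lower call without medullary GFP-positive library 2, and there were 7 lower calls without medullary GFP-negative library 1. Pecam1, at 33.5 ± 7.88 against 49.3 ± 22.3 CPM, was not called.

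Of 24 proliferation genes 13 fell in the medulla (18 adjusted over the list alone; camera adjusted p = 1.18e-07, and adjusted p = 0.237 with an estimated correlation), with Cdk1 8.90-fold and Mcm3 6.72-fold lower. Of 23 stress genes 1 rose and 14 fell (1 and 17 adjusted over the list alone; camera adjusted p = 1.68e-09, and adjusted p = 0.0713 with an estimated correlation), with Dusp1 5.27-fold and Zfp36 6.91-fold lower. Of 16 glucocorticoid-responsive genes 3 rose and 8 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0146, and adjusted p = 0.237 with an estimated correlation). All 13 mitochondrially encoded genes rose (13 adjusted over the list alone; camera adjusted p = 3.79e-07, and adjusted p = 0.237 with an estimated correlation), with mt-Nd4 3.17-fold higher, and their share of counts was 12.5% ± 2.82 against 4.61% ± 0.75. There were 7 proliferation and 5 mitochondrial calls without medullary GFP-negative library 1, 7 mitochondrial calls without medullary GFP-positive library 3, and 8 stress and 7 glucocorticoid-responsive calls without medullary GFP-negative library 2. Among 18 capsule and stem cell genes, of which 3 rose and 4 fell without passing the set test (3 and 5 adjusted over the list alone; camera adjusted p = 0.649), Sfrp1 stood at 203 ± 120 against 6.43 ± 5.84 CPM, while Gli1 stood at 0.058 ± 0.0532 against 0.193 ± 0.0145 CPM, near the floor. The Notch list (camera adjusted p = 0.832) had a median below 0 although the test pointed up.

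The GFP contrasts of the 2 tissues shared many genes. Of the genes higher in GFP-positive cells, 889 were called in both tissues, where independent lists would share 152.5 (odds ratio 21.5), and 1103 were lower in both, where independent lists would share 176.6 (odds ratio 33.8). Opposite calls numbered 14 and 15. The fold changes of the contrasts had a correlation of 0.557 across genes, which are not independent replicates. The contrasts have no library in common, but all libraries came from 6 mice in 3 pools, which the labels do not tie to libraries.

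**Figure D3:**
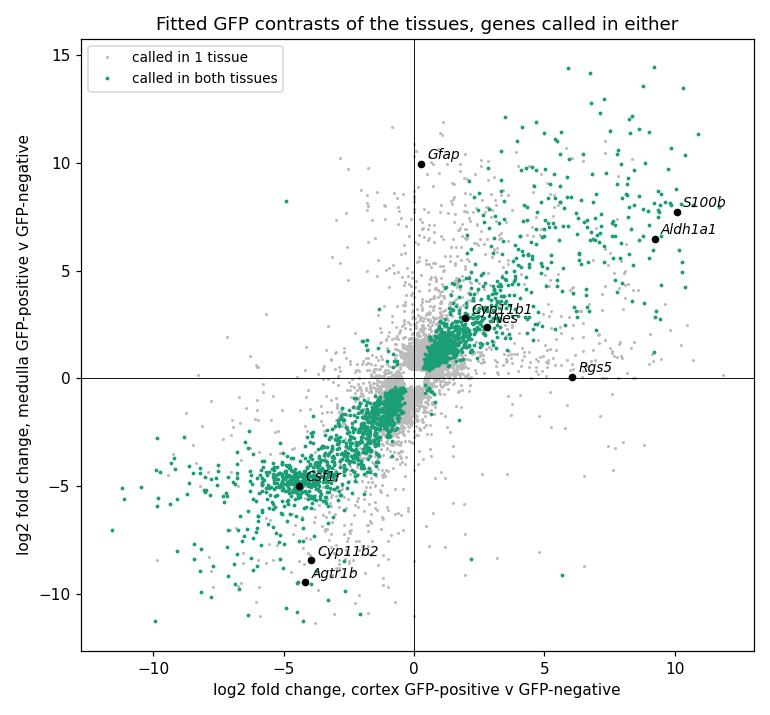
Fitted log2 fold change of GFP-positive over GFP-negative cells in the cortex (x axis) and in the medulla (y axis) for each gene called in at least 1 tissue. Green points are genes called in both tissues and grey points genes called in 1; most green points lie in the quadrants of equal sign, while Gfap and Rgs5 lie near 1 of the axes.

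An interaction term tested where the GFP contrast differed between the tissues. Of 14 zona glomerulosa genes 4 were called, all with a positive difference, cortex minus medulla (7 adjusted over the list alone; camera adjusted p = 2.87e-07, and adjusted p = 0.385 with an estimated correlation). None of them was called without cortical GFP-negative library 1, 2 or 3, and 2 were called without cortical GFP-positive library 3, medullary GFP-positive library 3 or medullary GFP-negative library 2. The difference was 4.50 on the log2 scale for Cyp11b2 (SE 0.742, edgeR adjusted p = 0.0261), 5.31 for Agtr1b (SE 0.959, edgeR adjusted p = 0.0302) and 2.53 for Dab2 (SE 0.475, edgeR adjusted p = 0.0336). The mural genes Rgs5 and Ndufa4l2 had differences of 5.99 (SE 1.08) and 3.89 (SE 0.534). Gfap, whose cortical levels were 1.64 ± 0.415 and 1.36 ± 0.272 CPM in the GFP-positive and GFP-negative gates, had a difference of -9.68 (SE 1.02, edgeR adjusted p = 0.00776). Differences of the same sign as that of Gfap were found for Gpsm2 (-6.17, SE 0.518) and Insc (-5.93, SE 1.06), which encode partners in spindle orientation, and for Olfml2a (-5.00, SE 0.69) and Col18a1 (-3.72, SE 0.549). Jun had a difference of 1.49 (SE 0.282).

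The interaction called 337 genes, 179 with a positive and 158 with a negative difference, cortex minus medulla. The signs were 122 positive and 270 negative with total counts alone, and 216 and 233 with no filter on low counts. The calls numbered 93 with age as a covariate, 578 with the stricter filter and 1595 with DESeq2. Age was not balanced over the medullary gates. The count fell to 169, 184 and 183 without cortical GFP-positive library 1, 2 or 3, to 74, 60 and 80 without cortical GFP-negative library 1, 2 or 3, and to 56 without medullary GFP-negative library 2. Of the genes named, Gpsm2, Gfap and Ndufa4l2 kept their call without any 1 library, of which Gfap and Ndufa4l2 lost it with voom (adjusted p = 0.107 and 0.101). The others lost it as follows (edgeR adjusted p): Cyp11b2 without cortical GFP-negative library 1, 2 or 3 (0.0563, 0.0638 and 0.0556) or medullary GFP-negative library 2 (0.0585), Col18a1 without cortical GFP-negative library 2 (0.0509) or medullary GFP-negative library 2 (0.0839), and Olfml2a without the latter (0.0672). Agtr1b lost the call without cortical GFP-positive library 3 (0.051), cortical GFP-negative library 1, 2 or 3 (0.0563, 0.0699 and 0.0636) or medullary GFP-positive library 1 or 3 (0.0561 and 0.0587). Rgs5 lost it without cortical GFP-positive library 2 or 3 (0.0517 and 0.0516), cortical GFP-negative library 3 (0.073), medullary GFP-positive library 1 or 3 (0.0525 and 0.0587) or medullary GFP-negative library 2 (0.0839). Without any 1 of the 6 cortical libraries the calls of Dab2, Insc and Jun ended too, as did that of Dab2 without medullary GFP-positive library 3 or medullary GFP-negative library 1 or 2 (0.053 to 0.0818 over all these), that of Insc without medullary GFP-positive library 2 or 3 (0.0517 to 0.0651) and that of Jun without medullary GFP-positive library 1 or 2 or medullary GFP-negative library 2 (0.0608 to 0.0846). With age as a covariate the calls of Cyp11b2 (0.0614), Agtr1b (0.0789), Dab2 (0.0584), Rgs5 (0.0725), Insc (0.0725) and Jun (0.0629) ended, with voom those of Agtr1b (0.219) and Rgs5 (0.0789), and with total counts alone that of Jun (0.0604).

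Of the lists, 7 passed the set test on the interaction, none of them with an estimated correlation. The zona glomerulosa list was 1 of them. Stress genes had 3 calls of 23, all higher (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.84e-06, and adjusted p = 0.385 with an estimated correlation). There was no stress call without any 1 of the 6 cortical libraries or medullary GFP-negative library 2, and 1 without medullary GFP-positive library 1. Pericyte genes had 3 calls of 24 (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00173, and adjusted p = 0.574 with an estimated correlation). There was 1 pericyte call without cortical GFP-positive library 2 or 3, cortical GFP-negative library 3, medullary GFP-positive library 1 or 3 or medullary GFP-negative library 2. Basement membrane genes had 2 lower calls of 15 (7 adjusted over the list alone; camera adjusted p = 6.58e-05, and adjusted p = 0.574 with an estimated correlation). There was none without cortical GFP-negative library 2 or medullary GFP-negative library 2, and 1 without any other cortical library. The cholesterol synthesis list pointed down with no call over all genes and 7 adjusted over the list alone (camera adjusted p = 2.97e-05, and adjusted p = 0.538 with an estimated correlation). It had 2 lower calls without medullary GFP-negative library 1 and 1 without medullary GFP-positive library 3. The endothelial list pointed up with 1 call (1 adjusted over the list alone; camera adjusted p = 1.71e-05, and adjusted p = 0.615 with an estimated correlation). That call was lost without any 1 library except medullary GFP-negative library 1, without which there were 2. The chromaffin list pointed up with 1 higher and 1 lower call (3 and 2 adjusted over the list alone; camera adjusted p = 0.000982, and adjusted p = 0.615 with an estimated correlation). There was 1 chromaffin call without medullary GFP-negative library 2, and there were 4 without cortical GFP-positive library 3.

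GFP-positive cells of the cortex and of the medulla differed in chromaffin and glial transcripts, which were higher in the medulla, and in steroid cell transcripts, which were higher in the cortex. Chga (chromosome 12, 102554969 to 102565027) stood at 3.52 ± 6.09 CPM in the cortex against 1777 ± 519 CPM in the medulla, a log2 change of -8.98 (SE 1.51, edgeR adjusted p = 0.00376). S100b stood at 19.1 ± 4.08 against 356 ± 160 CPM, a log2 change of -4.22 (SE 0.349, edgeR adjusted p = 0.000196). Cyp11b1 was 2.57-fold higher in the cortex (edgeR adjusted p = 0.000932) and Cyp11b2 55.5-fold higher (edgeR adjusted p = 0.00034). The test called 3236 genes, 1262 higher and 1974 lower in the cortex, of which 2237 changed at least 2-fold, and the groups did not overlap in 7214 genes, where chance gives 10%. The calls numbered 2107 without cortical GFP-positive library 1, 2156 without library 3 and 2006 without medullary GFP-positive library 2.

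Of 36 chromaffin genes 32 were lower in the cortex and none higher (34 adjusted over the list alone; camera adjusted p = 9.95e-32, and adjusted p = 0.0338 with an estimated correlation). Th fell by 9.98 on the log2 scale (SE 1.03), Dbh by 6.24 (SE 1.19), Gata3, a transcription factor of sympathoadrenal cells, by 6.48 (SE 0.398) and Scg5 by 5.16 (SE 0.44). Pnmt had no count in the cortex and was at least 2340-fold lower against a floor of 3 counts over the group, and was not called with voom (adjusted p = 0.191). Of 13 neuronal cytoskeleton genes 8 were lower (11 adjusted over the list alone; camera adjusted p = 1.5e-10, and adjusted p = 0.0561 with an estimated correlation). Slc35d3 was at least 960-fold and Spock3 at least 471-fold lower in the cortex on the same floor. The genes Elavl4, Nrsn1, Edn3, Rit2 and Nlrp6, with 1 or 2 counts in the cortex, had ratios of 1460 (95% counting interval 403 to 12000), 1510 (271 to 59700), 1250 (347 to 10400), 1610 (289 to 63700) and 1310 (234 to 51600). Of 34 Schwann and glial genes 26 were lower in the cortex (28 adjusted over the list alone; camera adjusted p = 7.28e-23, and adjusted p = 0.0592 with an estimated correlation). Ncam1 fell by 3.27 (SE 0.275), Gfap by 7.04 (SE 0.621) and Sox10 by 2.91 (SE 0.589, edgeR adjusted p = 0.0111, or 0.0508 without medullary GFP-positive library 2). Nes was 2.44-fold lower (edgeR adjusted p = 0.0392), a call that ended without cortical GFP-positive library 1, 2 or 3 (0.0788, 0.116 and 0.0891) and without medullary GFP-positive library 2 (0.133), with age as a covariate (0.0881) and in a fit of only the groups compared (0.0534).

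Of 29 steroidogenic genes 20 were higher in cortical than in medullary GFP-positive cells (23 adjusted over the list alone; camera adjusted p = 3.62e-16, and adjusted p = 0.0592 with an estimated correlation), among them Mc2r, the corticotropin receptor gene, by 4.17-fold. Star was 2.01-fold higher (edgeR adjusted p = 0.0461), a call that ended without any 1 of cortical GFP-positive libraries 1, 2 and 3 (0.0812, 0.117 and 0.0779) or medullary GFP-positive libraries 2 and 3 (0.101 and 0.0811), with other scalings (0.0555 with DESeq2 size factors and with total counts alone), with age as a covariate (0.0764) and in a fit of only the groups compared (0.0601). Nr5a1 was 2.29-fold higher (edgeR adjusted p = 0.04), a call that ended without cortical GFP-positive library 1 or 2 (0.0836 and 0.101) and without medullary GFP-positive library 2 or 3 (0.13 and 0.0999), and with age as a covariate (0.0686). Of 14 zona glomerulosa genes 12 were higher (13 adjusted over the list alone; camera adjusted p = 8.44e-20, and adjusted p = 0.0338 with an estimated correlation), with Agtr1a 6.16-fold and Dab2 11.1-fold higher. Shh, at 5.67 ± 3.54 against 1.03 ± 0.889 CPM, was not called, but was without medullary GFP-positive library 1 (edgeR adjusted p = 0.0361), with no filter (0.0384), with the stricter filter (0.0457) and with DESeq2 (0.00942). Other genes with large increases were Elovl7 (15.6-fold), Smpx (13.7-fold), Ctxn3 (13.6-fold), Caln1 (12.1-fold) and Vsnl1 (10.6-fold), with edgeR adjusted p values between 0.000137 and 0.0126. Nkd1 stood at 30.7 ± 4.70 against 2.24 ± 0.195 CPM, and of 17 Wnt targets 4 were higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.00201, and adjusted p = 0.149 with an estimated correlation).

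Of 16 Notch genes 6 were lower in cortical GFP-positive cells (6 adjusted over the list alone; camera adjusted p = 0.0136, and adjusted p = 0.181 with an estimated correlation), with the effector genes Hey2 at 1.90 ± 1.78 against 67.0 ± 26.3 CPM and Heyl at 6.69 ± 0.867 against 81.3 ± 42.6 CPM. Of 23 stress genes 12 were lower (12 adjusted over the list alone; camera adjusted p = 1.91e-05, and adjusted p = 0.149 with an estimated correlation), with Fos at 438 ± 153 against 1473 ± 318 CPM. Of 16 glucocorticoid-responsive genes 9 were lower (11 adjusted over the list alone; camera adjusted p = 1.2e-06, and adjusted p = 0.0561 with an estimated correlation), with the glucocorticoid receptor gene Nr3c1 2.16-fold lower. Macrophage genes had 5 lower calls of 24 (14 adjusted over the list alone; camera adjusted p = 3.19e-06, and adjusted p = 0.293 with an estimated correlation). These numbered 3 without cortical GFP-positive library 1 or medullary GFP-positive library 2, 8 without cortical GFP-positive library 2 and 10 without medullary GFP-positive library 3. Proliferation genes had 4 higher calls of 24 (5 adjusted over the list alone; camera adjusted p = 0.00671, and adjusted p = 0.455 with an estimated correlation), and 1 without cortical GFP-positive library 1 or medullary GFP-positive library 2 or 3. Basement membrane genes had 4 lower calls of 15 (7 adjusted over the list alone; camera adjusted p = 0.00643, and adjusted p = 0.446 with an estimated correlation). Of 18 capsule and stem cell genes 5 were higher and 1 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.0447, and adjusted p = 0.369 with an estimated correlation), and of 12 reporter and progenitor genes 2 were higher and 4 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.0452 for a decrease, and adjusted p = 0.178 with an estimated correlation). Of 22 cholesterol synthesis genes 2 were lower (2 adjusted over the list alone; camera adjusted p = 0.0379, and adjusted p = 0.455 with an estimated correlation), and without medullary GFP-positive library 2 there were 3 calls of capsule and 1 of cholesterol synthesis genes. The pericyte list did not pass the set test (camera adjusted p = 0.855), and camera and fry pointed in opposite directions for it. Rgs5 (52.2 ± 21.3 against 135 ± 77.4 CPM), Pecam1 (18.8 ± 11.4 against 33.5 ± 7.88 CPM) and Gli1 (0.683 ± 0.569 against 0.058 ± 0.0532 CPM) were not called.

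GFP-negative cells were compared between the cortex and the medulla as well. Most chromaffin genes were lower on the cortical side, and steroid cell transcripts were present on both sides. Chgb and Scg2, which encode granule proteins, had no count in the cortex against 3408 ± 1060 and 1258 ± 533 CPM in the medulla (SD, n = 2), so they were at least 91300-fold and 33800-fold lower against a floor of 3 counts over the group. Hsd3b1, an enzyme of steroid synthesis, stood at 17160 ± 2550 against 5022 ± 2420 CPM, a 3.42-fold difference (edgeR adjusted p = 0.00268). The test called 3892 genes, 1683 higher and 2209 lower in the cortex, of which 2663 changed at least 2-fold, and the groups did not overlap in 10344 genes. With total counts alone most calls were higher (2280 higher and 2043 lower). The calls numbered 2141 without cortical GFP-negative library 1 and 1411 without medullary GFP-negative library 2.

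Of 36 chromaffin genes 31 were lower in cortical GFP-negative cells (34 adjusted over the list alone; camera adjusted p = 2.67e-30, and adjusted p = 0.0348 with an estimated correlation). Of the 36, Scg5 stood at 49.4 ± 10.7 CPM in the cortex and Cyb561 at 59.1 ± 4.85 CPM, both chosen after their values were seen. On the same floor Npy was at least 14200-fold, Dbh at least 9610-fold, Cox8b at least 8440-fold, Gal at least 5310-fold and Pnmt at least 179-fold lower. Chga, with 3 counts in the cortex, had a ratio of 51100 (95% counting interval 17500 to 248000), Th, with 1 count, a ratio of 37500 (6730 to 1480000), and S100b, with 1 count, a ratio of 133 (23.2 to 5310). Gata3 fell by 7.06 on the log2 scale (SE 0.424). Of 34 Schwann and glial genes 14 were lower (2 higher and 18 lower adjusted over the list alone; camera adjusted p = 6.45e-08, and adjusted p = 0.208 with an estimated correlation). Of 24 macrophage genes 14 were lower (18 adjusted over the list alone; camera adjusted p = 1e-08, and adjusted p = 0.208 with an estimated correlation), with Csf1r 4.81-fold and Mrc1 7.76-fold lower. Without any 1 of the 5 libraries 4 to 8 macrophage calls were left. Of 30 endothelial genes 13 were lower (21 adjusted over the list alone; camera adjusted p = 1.09e-07, and adjusted p = 0.356 with an estimated correlation), with Eng 5.40-fold and Emcn 7.14-fold lower. Medullary GFP-negative library 2 stood at 258 CPM of Emcn against 64.3 CPM in library 1, and without it 1 endothelial call was left, with 5 without cortical GFP-negative library 1 or 3. Of 24 pericyte genes 3 were higher and 5 lower (4 and 7 adjusted over the list alone; camera adjusted p = 0.0237, and adjusted p = 0.46 with an estimated correlation), with Rgs5 at 0.770 ± 0.953 against 128 ± 14.1 CPM and Ndufa4l2 at 0.413 ± 0.0995 against 167 ± 24.9 CPM. There were 4 pericyte calls without medullary GFP-negative library 2 and 5 without cortical GFP-negative library 1. Of 23 stress genes 1 was higher and 16 lower (1 and 19 adjusted over the list alone; camera adjusted p = 7.18e-16, and adjusted p = 0.0348 with an estimated correlation), with Dusp1 3.81-fold and Zfp36 5.11-fold lower. Of 16 glucocorticoid-responsive genes 11 were lower (1 higher and 12 lower adjusted over the list alone; camera adjusted p = 8.54e-10, and adjusted p = 0.0348 with an estimated correlation), with Fkbp5 4.18-fold lower.

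Of 29 steroidogenic genes 17 were higher and 1 lower in cortical GFP-negative cells (25 and 2 adjusted over the list alone; camera adjusted p = 1.17e-11, and adjusted p = 0.103 with an estimated correlation). Without medullary GFP-negative library 2 there were 6 steroidogenic calls. Cyp11b1 was 4.54-fold and Star 2.55-fold higher. Of 14 zona glomerulosa genes 6 were higher (9 adjusted over the list alone; camera adjusted p = 2.73e-05, and adjusted p = 0.208 with an estimated correlation). Without cortical GFP-negative library 1 or 2 or medullary GFP-negative library 2, 1 was higher. Cyp11b2, at 1183 ± 219 against 483 ± 119 CPM, was not called, but was in a fit of only the groups compared (edgeR adjusted p = 0.0117) and with voom (adjusted p = 0.00143). Among the largest increases were those of Adh7 (17.6-fold), Mybpc1 (9.82-fold), Aox1 (5.72-fold), Wnt5a (5.25-fold), Gnat2 (4.59-fold), Pla2g2d (4.50-fold) and Arhgap24 (3.99-fold). Nes was 3.29-fold and Pecam1 3.86-fold lower in the cortex. Of the genes named for this comparison, 11 lost the call without medullary GFP-negative library 2: Adh7 (edgeR adjusted p = 0.0701), Arhgap24 (0.0745), Cox8b (0.0671), Emcn (0.166), Gnat2 (0.077), Mybpc1 (0.165), Nes (0.144), Pecam1 (0.194), Pla2g2d (0.0713), Pnmt (0.136) and Star (0.171). Without medullary GFP-negative library 1, Adh7 (0.0633), Arhgap24 (0.16) and Pnmt (0.0823) lost it. Without cortical GFP-negative library 1 the calls of Cox8b (0.0607), Mybpc1 (0.0528), Nes (0.0536), Pecam1 (0.059), Pnmt (0.0877) and Star (0.0555) ended, without library 2 those of Arhgap24 (0.092), Cox8b (0.0568), Mybpc1 (0.078), Pnmt (0.0859) and Star (0.0623), and without library 3 those of Arhgap24 (0.0663), Cox8b (0.0549), Pecam1 (0.0653) and Pnmt (0.0832). With voom Adh7 (adjusted p = 0.0503), Gal (0.0543), Nes (0.0772), S100b (0.107) and Pnmt (0.294) were not called.

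The other lists that passed the set test between the GFP-negative gates were the neuronal cytoskeleton list, with 8 of 13 genes lower (10 adjusted over the list alone; camera adjusted p = 1.09e-07, and adjusted p = 0.136 with an estimated correlation), the Notch list, with 9 of 16 lower (13 adjusted over the list alone; camera adjusted p = 2.09e-05, and adjusted p = 0.0777 with an estimated correlation), the Wnt targets, with 4 of 17 higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.0376, and adjusted p = 0.306 with an estimated correlation), and the mitochondrially encoded genes, with 1 of 13 higher (none adjusted over the list alone; camera adjusted p = 0.00987, and adjusted p = 0.462 with an estimated correlation). Without medullary GFP-negative library 2 there were 4 Notch and 2 Wnt target calls, without cortical GFP-negative library 1 or 2 there were 3 Wnt target calls, and without any 1 of the 5 libraries there was no mitochondrial call. Sox10 had 9 counts in cortical and none in medullary GFP-negative libraries, and Nr5a1 (285 ± 65.8 against 141 ± 87.6 CPM), Shh (29.7 ± 6.40 against 19.9 ± 2.10 CPM) and Gli1 (0.0866 ± 0.117 against 0.193 ± 0.0145 CPM) were not called. Nr5a1 was called without medullary GFP-negative library 1 (edgeR adjusted p = 0.013), with voom (adjusted p = 0.0384) and with DESeq2 (adjusted p = 0.0474).

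The authors' deposited table for the cortical GFP contrast lists 925 genes at the same adjusted p threshold, 923 of them called here. The authors' deposited table for the medullary contrast lists 1558, with 1553 called here. The authors' deposited table for GFP-positive cells of the tissues lists 1039, with 1036 called here. No gene was called in opposite directions here and in the authors' deposited table of any comparison. The p-values of the authors' deposited table behave as a test against a 2-fold change. A like test of these fits, chosen after the data were seen, called 979, 1747 and 1004 genes, of which 844, 1452 and 878 were among those 925, 1558 and 1039 of the authors' deposited table.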

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

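The tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the libraries, which were chosen before. The interaction term flagged 337 genes whose GFP contrast differs between cortex and medulla (edgeR's quasi-likelihood test). Among those named, the difference of the contrasts, cortex minus medulla, was 4.502 on the log2 scale for Cyp11b2, 5.308 for Agtr1b, 2.527 for Dab2, 5.992 for Rgs5, 3.89 for Ndufa4l2 and 1.491 for Jun. The difference was negative for Gfap (-9.677), Gpsm2 (-6.173), Insc (-5.93), Olfml2a (-5.002) and Col18a1 (-3.719). Without medullary GFP-negative library 2 the count was 56. Outside the genes, 10 counts lay on external spike-in sequences over all libraries. For each of the 2 comparisons of 3 against 3 libraries, the 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave as many calls, with 3078 genes in the cortical GFP contrast and 3236 between GFP-positive cells of the tissues, and the highest of the other splits gave 0.

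Glial transcripts stood in cortical GFP-positive libraries at a median of 8.42%, 10.9% and 7.73% of their medullary GFP-positive level over 23 genes, and medullary cells carried over in the dissection are a candidate source. If medullary GFP-positive cells of all kinds came along, chromaffin genes would stand at a like share, and they stood at 3.21%, 0.512% and 0.211% over 32 genes. The glial genes were those called higher in cortical GFP-positive cells, which favours a high share, while chromaffin genes were chosen by medullary level alone. Over 23 glial genes chosen by medullary calls and low cortical GFP-negative levels, the median shares were 8.26%, 10.7% and 7.31%. Cortical GFP-positive libraries 2 and 3 were set apart from library 1 after the ratios of the 2 shares were seen. The ratio was taken over all chromaffin genes and those above 5 minimum levels, chosen after a first look at 500 CPM alone. Its highest value in libraries 2 and 3 was 0.047, under the bound of 0.25. The 95% intervals from 10000 resamplings of the genes were 0.00879 to 0.245 and 0 to 0.156. They treat the genes of 1 library as independent, so they are too narrow where genes vary together. Th and Chga had no count in either library. Dbh had counts in library 3, Chgb and Scg2 in library 2, and Scg3 and Gch1 in both. The low ratios argue against this source there at a like share, if narrowly in library 2 by its interval. In library 1 the ratio was 0.382 over all chromaffin genes and 0.172 over the 5 above 500 CPM, with Th at 1.38 CPM against 467 CPM in the medulla and Chga at 10.6 against 1777 CPM, which leaves it open for that library. Medullary glia alone would bring their transcripts at 1 common share, and over 23 glial genes held by cortical GFP-negative cells at under 5% of that level the mean shares ran from 0.758% (Gfap) to 25.6% (Kcna1), with 8 genes over 4-fold off the median share in some library and 1, or 4.3%, in every library (Gfap), which leaves this source open, as are glial cells resident in the cortex, the tissue difference that the design names, which were not tested.

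The split of steroid cell transcripts by zone between the gates was seen in both tissues, with Cyp11b1 higher and Cyp11b2 lower in GFP-positive cells. Free RNA from broken cortical cells would keep zona glomerulosa and other steroidogenic genes in 1 ratio in both gates of a tissue, and the gates lay at least 1.9 apart on the log2 scale with no overlap of libraries, which argues against it as the whole cause. A smaller share of steroid cells in the GFP-negative gate would lower both lists there. In both tissues zona glomerulosa genes were higher in that gate, by at least 1.23 in mean log2 CPM. This argues against a smaller share as the whole cause. The gap is part of the pattern itself and so no separate test, and a smaller share stays open as a part of the cause. Sorting on the autofluorescence of steroid cells could not be examined, since 0 entries of the count table are named for the reporter, so it stays open. A difference in reporter activity between zones, the biological reading, also stays open.

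Steroid cell transcripts in medullary libraries may come from cortical cells carried over. In medullary GFP-negative libraries zona glomerulosa genes stood at 50.7% and 33.7% of their cortical GFP-negative level and other steroidogenic genes at 50.4% and 30.1%, a highest ratio of 1.12, which is consistent with carry-over of cortical GFP-negative cells of all zones. In medullary GFP-positive libraries the shares were 11.9%, 18.5% and 12.2% against 55.2%, 40.4% and 45.3%. Ratios up to 0.457 argue against carry-over of cortical GFP-positive cells of all zones at 1 share. Steroid-producing cells that belong to the medulla were not tested as a source and stay open.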

How the results depend on the processing

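The test against a log2 fold change of 1 was chosen after seeing the data, and the other alternatives before. It called 979 genes in the cortical and 1747 in the medullary GFP contrast, 1004 between GFP-positive and 642 between GFP-negative cells of the tissues and 23 in the interaction, with 269 higher in both tissues, since it asks for a larger change. Under the other planned settings these counts lay within 1.5 times the reported ones (2815 to 4616, 3268 to 5927, 2562 to 4425, 3339 to 5461, and 681 to 1272 shared), except those of the interaction: 578 with the stricter filter, 93 with age as a covariate, 176 with the replicate block and 1595 with DESeq2, and the cause was not tested. With total counts alone the share of higher calls was 38% against 48.5% in the cortical contrast, 53.6% against 47.9% in the medullary, 31.2% against 39% between GFP-positive and 52.7% against 43.2% between GFP-negative cells, and 31.1% against 53.1% in the interaction, and the median of all genes moved by -0.101 in the first and -0.168 in the last. Lists past the threshold numbered 14, 14, 15, 13 and 7, and 0, 0, 2, 3 and 0 with an estimated correlation; fry gave 0 for the interaction. Leaving out 1 library gave 1959 to 2405, 2956 to 3922, 2006 to 2874, 1411 to 3720 and 56 to 489 calls in the 5 comparisons, 599 to 917 shared genes, and 14 to 16, 11 to 16, 12 to 15, 12 to 13 and 7 to 11 lists; the lowest counts of calls came without cortical GFP-negative library 3 (1959), medullary GFP-negative library 2 (2956, 1411 and 56) and medullary GFP-positive library 2 (2006). A lone medullary GFP-negative library is assumed to vary like the other groups. Same-number libraries correlated weakly in their deviations, at 0.034 to 0.071 in the cortical contrast, none over 0.1. Other pairs there stood at -0.054 to -0.0049. Between GFP-positive cells of the tissues the values were 0.026 to 0.043 against -0.023 to -0.0078. In both comparisons of 3 against 3, 6 of 6 libraries correlated best with their own number, and in the others 3 of 5 and 2 of 5. A weak pairing by number therefore stays open. The replicate block gave 2815, 3985, 2908 and 3339 calls in the other comparisons. Of 550 results of genes the rule names, 402 were called, of which 0 changed sign under any alternative, and 25 of 148 not called did. For the 183 results of genes named in the text that were run, 160 of them called, the alternatives gave 3235 values: 3024 kept their direction and side of the threshold, 163 fell short of it, 19 passed it and 29 changed sign or, in 1 for Sox10, reached 0. The 19 belong to 6 results not called. These are Shh and Chga in the cortex, Shh between GFP-positive cells, Pnmt in the medulla, and Cyp11b2 and Nr5a1 between GFP-negative cells. Shh in the cortex passed with total counts alone, no filter, the stricter filter, only the groups compared, voom and DESeq2. The 29 all belong to results not called, and the cause was not tested. On the log2 scale, Nr5a1 in the cortex stood at -0.016 with total counts alone. In the medulla Nr5a1 stood at 0.0085 with total counts alone, 0.084 with the replicate block, 0.23 with age as a covariate and 0.016 with voom, Chga at 0.37 with the block and 1.09 with age, Rgs5 at -0.19 with the block, -0.12 with age and -0.028 with voom, and Th at -0.041 without the 20 most counted genes in TMM, -0.024 with the stricter filter, -0.026 with only the groups compared and -0.0035 with DESeq2. Leaving out 1 library gave, in the cortex, -3.07 to 9.41 for Chga, -1.79 to 6.47 for Th, -0.093 to 0.30 for Nr5a1 and -0.060 to 0.85 for Pecam1, in the medulla -0.36 to 0.20 for Chga, -0.61 to 0.76 for Nr5a1, -0.49 to 0.36 for Rgs5 and -0.49 to 0.78 for Th, and between GFP-negative cells 0 to 5.07 for Sox10. Calls of named genes that ended numbered 16 with voom (adjusted p of 0.0503 to 0.377), 9 with age as a covariate (0.0584 to 0.0881), 9 with the replicate block (0.0515 to 0.077, Dbh in the cortex, Nes, Star and Nr5a1 between GFP-positive and Pnmt between GFP-negative cells, and Cyp11b2, Agtr1b, Dab2 and Insc in the interaction), 2 with total counts alone, 2 in fits of only the groups compared, 1 with DESeq2 size factors, 26 without some library (0.0508 to 0.194) and 30 in the test against a log2 fold change of 1. Of the 11 genes named for the interaction, 1 (Gpsm2) was called under every alternative set beforehand. Depth limits genes near 0.103 to 0.162 CPM.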

Other observations

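The genes in this paragraph were chosen after their values were seen, and no explanation was tested. Abcb1b, which encodes a drug efflux pump (ENSMUSG00000028970, chromosome 5, 8798147 to 8866315, mm10), was higher in GFP-positive than in GFP-negative cells of both tissues. It stood at 2941 ± 271 CPM (SD, n = 3) against 39.0 ± 5.75 CPM (SD, n = 3) in the cortex, a log2 difference of 6.24 (SE 0.298, edgeR adjusted p = 1.26e-05). In the medulla it stood at 2815 ± 1090 CPM (SD, n = 3) against 27.4 ± 1.08 CPM (SD, n = 2), a log2 difference of 6.68 (SE 0.366, edgeR adjusted p = 2.55e-05). Its neighbour and paralog Abcb1a was higher as well, by 4.26 in the cortex (SE 0.434, edgeR adjusted p = 0.000313) and 2.86 in the medulla (SE 0.473, edgeR adjusted p = 0.00212), with reads that can be split between both genes. Within 500 kb, 7330423F06Rik, which lies inside Abcb1b on the same strand, was higher by 8.34 (SE 0.941, edgeR adjusted p = 0.000467) in the cortex and 6.93 (SE 1.06, edgeR adjusted p = 0.00138) in the medulla. In the medulla the processed pseudogene Gm17936 was higher by 2.49 (SE 0.415, edgeR adjusted p = 0.00218), and Dbf4 fell by 2.43 (SE 0.751, edgeR adjusted p = 0.0436). The other genes tested in that window, among them Slc25a40 and Rundc3b, were not called in either tissue. Mgst2, a microsomal glutathione transferase gene, was higher by 8.88 in the cortex (SE 0.531, edgeR adjusted p = 3.8e-05) and by 10.00 in the medulla (SE 0.684, edgeR adjusted p = 3.15e-05).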
